A study of Escherichia coli with 12 samples.

How the data were processed

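Gene expression was measured by RNA sequencing in 12 libraries of Escherichia coli HS, 4 for each of 3 growth media. Per the labels' protocols, bacterial RNA was purified with the RiboPure kit and freed of DNA, ribosomal RNA was depleted, and libraries were made with the NEBNext Ultra kit. Per the submitters' processing notes, Trim Galore, STAR, featureCounts, edgeR, DESeq2 and DESeq were used, with no version, role or order stated. The genome build, the annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. The deposited count table holds raw whole-number counts for 3452 genes, named by E. coli HS locus tags, of which 3122 have a gene symbol and 330 do not. The table holds hardly any gene with few counts, and the rule by which the authors left such genes out is not given in the sources used here. A further table holds the authors' normalized signal, which was found to equal the counts divided by 1 factor per library, 0.736 to 1.29, and these factors equal median-of-ratios size factors computed from the counts. Per the file headers, the same table gives the authors' log2 fold changes and their raw and adjusted p-values for the 3 comparisons. The adjusted p-values are missing for 3 genes. By the authors' deposited p-values, 622 genes were higher and 604 lower in the doxorubicin than in the QVD supernatant, 1026 and 961 in the doxorubicin supernatant against medium, and 737 and 780 in the QVD supernatant against medium. Of these calls, 1120, 1944 and 1449 were also made here.

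Each column was matched to its library by name, through the library name in the labels. Libraries of 1 group differed beyond sampling noise in every pair (chi-square per degree of freedom 8.77 to 114), so none was treated as a duplicate. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The fit used all 12 libraries with group as the only term, TMM scaling, filterByExpr (3451 genes kept, 1 dropped) and robust quasi-likelihood dispersions, with a common biological coefficient of variation of 0.134. Each comparison was tested with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p below 0.05 were called. Standard errors are the log2 fold change divided by the square root of its F statistic. Levels are CPM with TMM-scaled library sizes.

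Gene lists were 54 sets of gene symbols for pathways and regulons that the drug, released nutrients, oxygen, metals or growth phase could alter. Lists, tests, alternatives and the rule for named genes were chosen before the data were examined. Symbols were matched without regard to case, and older symbols through a name table of E. coli K-12 MG1655, in which 3063 of the symbols in the count table were found; it served for names only. The 52 lists with at least 4 tested genes were tested with camera on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Counts of list members are given over all genes tested and adjusted over the list alone. Of the calls, arginine biosynthesis in both comparisons of the doxorubicin supernatant held with a correlation estimated from the data. fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 34, 36 and 22 lists, and its mixed test, for change in either direction, called 48, 51 and 44.

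Named genes were, per comparison, those called with a symbol, a mean of at least 10 CPM and no overlap between the groups that had the largest changes (6 per direction, or 4 for the QVD supernatant against medium, with at most 2 genes sharing their first 3 letters). Added to these were the 2 members with the smallest p in up to 6 called lists and in the SOS, fermentation, purine and pyrimidine lists, and recA, sulA, pflB and purF in every comparison. This gave 64 genes. Members named because they moved against their list, torC, dnaJ, yafD and the genes described under the additional observations were chosen after their values were seen. A set of 8 genes without a symbol was also chosen then, as those with a within-group SD of at least 0.5 log2 units that correlated with the most variable of them at 0.9 or more; they are ECHS_RS01020, ECHS_RS01035, ECHS_RS13565, ECHS_RS13575, ECHS_RS19580, ECHS_RS19590, ECHS_RS20055 and ECHS_RS20070. More than once in the table occur 25 symbols, and genes with a near-identical copy are uncertain because the treatment of shared reads is not given in the sources used here. Overlapping and antisense genes are uncertain because the strand setting is not given.

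On simulated counts with the real means, library sizes and 200 changed genes among 3451, made for the doxorubicin against the QVD supernatant and run 5 times, the test recovered 57.61% of changes of 0.5 log2 units, 93.73% of changes of 1 and 99.09% of changes of 2, with 5.44% false among its calls. In the unchanged comparison of the QVD supernatant with medium it called 0 genes. By these shares, changes of single genes well below 0.5 log2 units are not reliably detectable where 200 genes change. More genes than that were called in every real comparison, which makes the adjusted threshold less strict. The shares therefore do not carry over to the real comparisons. Of lists shifted by 0.5 log2 units 25 of 25 were called, and 1 of 75 unshifted lists. These lists were random genes drawn independently of each other. Their rate of false calls therefore does not carry over to the real lists, whose genes can vary together.

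Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0 (Wald test), fits of the compared groups alone, the replicate number as a block, a term for the suffix of the library names, libraries with the suffix L1 alone, camera with an estimated correlation, fry, and leaving out each library in turn. A term for the 8 unnamed genes and a fit of the 7 libraries in which they take under 0.2% of counts were added after seeing the data. A term for the mean log2 CPM of the ribosomal protein genes served as a measure of growth state. Overlaps between comparisons that share libraries were set beside 50 simulations of unchanged groups, in which genes were drawn independently of each other. Genes of phage origin were not analysed here, since the list was to be taken from product descriptions, and effects of GC content and gene length were not analysed here because no genome was used.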

Results

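The series addressed how Escherichia coli responds when it grows on material released by dying epithelial cells. E. coli HS, a commensal strain, was grown aerobically at 37 °C and 200 rpm to mid-log phase in filtered supernatants free of mammalian cells. The supernatants came from CT26 cells, a murine colon carcinoma line, after 24 h with 20 µg/ml doxorubicin, a DNA-damaging anthracycline used to induce apoptosis. A parallel supernatant came from cells that also received 30 µM QVD, a pan-caspase inhibitor that blocks apoptosis, and control cultures grew in DMEM with 10% FBS. These are called the doxorubicin supernatant, the QVD supernatant and medium. RNA sequencing after removal of ribosomal RNA gave 4 libraries per group. Gene counts per library, in units of 10⁶, totalled 5.54 to 8.33. Their means were 7.20 ± 0.787 in medium, 6.80 ± 1.27 in the doxorubicin supernatant and 7.04 ± 0.701 in the QVD supernatant (SD, n = 4). The labels do not state that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

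The 3 groups separated on the first pair of principal components of log2 CPM (counts per 10⁶ counts). The first component, with 59.9% of the variance, placed medium at -29.0 to -11.8, the QVD supernatant at -2.10 to 1.75 and the doxorubicin supernatant at 19.7 to 23.2. On the next component, with 16.8% of the variance, the QVD libraries lay at -15.1 to -9.70 and the other libraries at 3.26 to 9.78. The mean log2 CPM of the ribosomal protein genes, a measure of growth state, was 10.37 to 11.30 in medium. It was 11.05 to 11.12 in the QVD and 11.61 to 11.69 in the doxorubicin supernatant. For the general stress genes the mean was 6.483 to 7.101, 5.733 to 5.977 and 5.425 to 5.593 in the same order. Cultures at a like growth phase are therefore not shown by these levels, and a difference in growth state remains open in every comparison. A set of 8 genes listed by locus tag alone varied together within groups, and the sources used here do not say what they encode. They took 0.0618% to 0.630% of the counts in medium, 0.0441% to 0.169% in the doxorubicin supernatant and 0.117% to 1.14% in the QVD supernatant. The shares were under 0.2% in 2 of the 4 medium libraries, all 4 doxorubicin libraries and 1 of the 4 QVD libraries. The level of dnaJ, a heat shock chaperone gene, followed the same libraries, with ranges of 2.56 log2 units within medium, 0.65 within the doxorubicin supernatant and 2.69 within the QVD supernatant. So did yafD, which is not in the heat shock list. It spanned 3.55 to 7.35 log2 CPM in medium, 3.77 to 3.96 in the doxorubicin and 3.88 to 6.78 in the QVD supernatant. For dnaJ the doxorubicin and QVD supernatants differed by -1.77 ± 0.74 log2 units (SE, adjusted p = 0.0978), and by 0.20 ± 0.50 when the mean level of the 8 genes was a term in the fit.

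**Figure D1:**
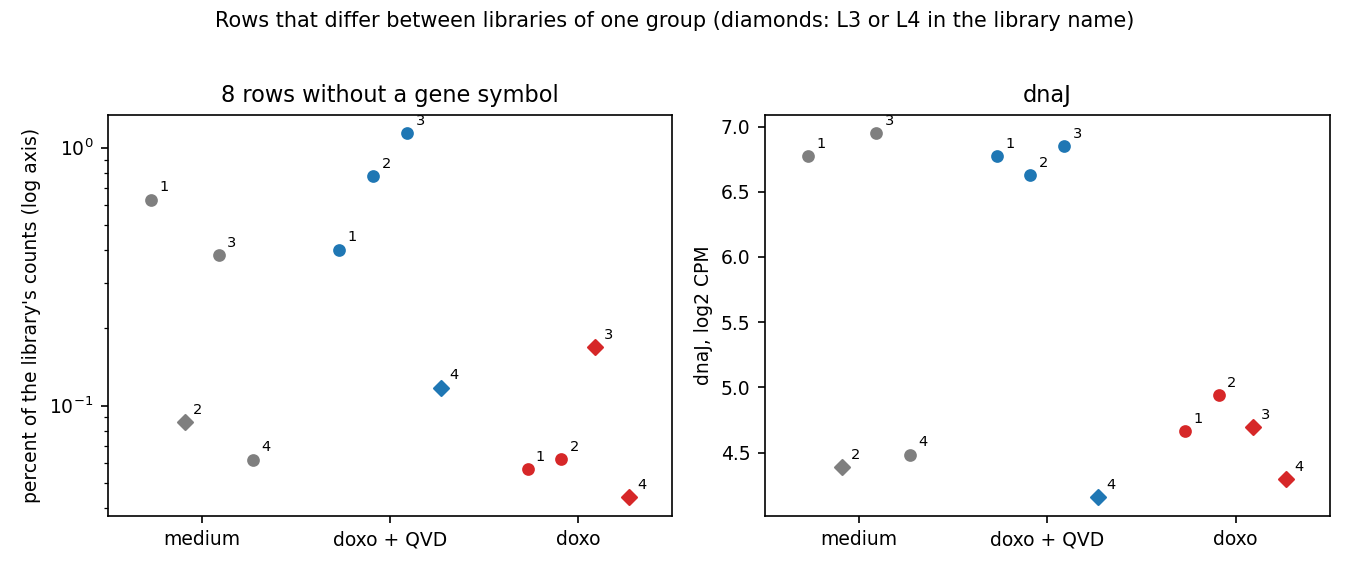
Left, the percent of each library's counts taken by 8 genes without a symbol (log axis); right, dnaJ in log2 CPM, with 1 point per library, its replicate number beside it and diamonds for libraries whose names carry L3 or L4. The shares span 0.0618% to 0.630% within medium and 0.117% to 1.14% within the QVD supernatant, and all 4 doxorubicin libraries lie at or below 0.169%.

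The doxorubicin and QVD supernatants both came from drug-treated cells, and this comparison asks what differs when death was not inhibited. In the doxorubicin supernatant, genes for sulfate reduction, arginine and histidine synthesis, maltodextrin use and ribosomal proteins were higher, and genes for zinc uptake, potassium and osmotic stress and acid resistance were lower. Of these list calls arginine alone held with an estimated correlation (adjusted p = 0.153 to 0.440 for the others). The steepest rises were in cysP (ECHS_RS12665), which encodes a periplasmic thiosulfate-binding protein, and cysJ (ECHS_RS14315), which encodes a sulfite reductase subunit. cysP rose 20.8-fold (log2 4.38 ± 0.15 SE, adjusted p = 2.22e-11), from 18.6 ± 2.54 to 386 ± 66.7 CPM (SD, n = 4). cysJ rose 13.6-fold (3.76 ± 0.12, adjusted p = 3.88e-12), from 26.7 ± 1.15 to 363 ± 58.2 CPM. The steepest falls included zinT (ECHS_RS10260), for a periplasmic zinc-binding protein, which fell by 3.04 ± 0.29 on the log2 scale (adjusted p = 3.23e-06), from 56.3 ± 18.6 to 6.81 ± 0.304 CPM. Of 3451 genes tested, 587 were higher and 536 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 100 and 63 of these differed at least 2-fold. The balance turned without medium replicate 2 (511 higher, 642 lower) or 3 (539, 648) and without QVD replicate 1 (414, 535), 2 (431, 548), 3 (391, 509) or 4 (379, 508). It also turned with RLE scaling (561, 563), with the term for the 8 unnamed genes (244, 250) and with libraries low in them (113, 140).

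Amino acid biosynthesis genes rose in several pathways. Of the 17 tested genes for cysteine biosynthesis and sulfate assimilation, 13 rose and 1 fell, with a median log2 change of 1.64 (camera adjusted p = 3.38e-10, adjusted p = 0.153 with an estimated correlation). Adjusted over the list alone, 13 rose and 2 fell, and the member that fell over all genes was cysB, the pathway's activator (-0.27 ± 0.09). Conversely, cyuP (ECHS_RS16270) and cyuA (ECHS_RS16265), for a cysteine transporter and a cysteine-degrading enzyme, fell, with log2 changes of -2.88 ± 0.23 and -2.49 ± 0.19 (adjusted p = 3.10e-07 and 1.56e-07). All 8 tested arginine biosynthesis genes rose, also when adjusted over the list alone, with a median of 1.76 (camera adjusted p = 1.76e-10, adjusted p = 0.00367 with an estimated correlation). argH (ECHS_RS20630), for argininosuccinate lyase, rose 3.50-fold (1.81 ± 0.11, adjusted p = 9.56e-09). argA (ECHS_RS14605), for the pathway's initial enzyme, rose 3.09-fold (1.63 ± 0.08, adjusted p = 1.03e-09). All 8 histidine biosynthesis genes rose, also when adjusted over the list alone, with a median of 1.15 (camera adjusted p = 2.32e-08, adjusted p = 0.225 with an estimated correlation). hisD (ECHS_RS10725) rose by 1.45 ± 0.13 and hisA (ECHS_RS10745) by 1.12 ± 0.12 log2 units (adjusted p = 1.09e-06 and 3.49e-06). Of 14 branched-chain amino acid genes, 7 rose (9 adjusted over the list alone, median 0.32, camera adjusted p = 0.00712, adjusted p = 0.316 with an estimated correlation). Of 11 methionine genes, 4 fell by either adjustment, over all genes or adjusted over the list alone (median -0.25, camera adjusted p = 0.0364, adjusted p = 0.364 with an estimated correlation). The methionine call was lost without doxorubicin replicate 3 (adjusted p = 0.0760) and without QVD replicate 1 (adjusted p = 0.0583). It was also lost with libraries low in the 8 unnamed genes, 1 of them from the QVD supernatant, at a median of -0.25 (adjusted p = 0.0822), and with fry the adjusted p was 0.00494.

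Genes for maltose, lactose and trehalose use also rose, in 11 of 14 tested genes and in 13 adjusted over the list alone, with a median of 1.72 (camera adjusted p = 4.31e-09, adjusted p = 0.153 with an estimated correlation). malP (ECHS_RS17800), for maltodextrin phosphorylase, rose 5.44-fold (2.44 ± 0.14, adjusted p = 7.66e-09). malS (ECHS_RS18590), for a periplasmic alpha-amylase, rose 2.81-fold (1.49 ± 0.11, adjusted p = 7.04e-08). The anaerobic glycerol-3-phosphate dehydrogenase gene glpA (ECHS_RS11810) rose 7.68-fold (2.94 ± 0.27, adjusted p = 9.25e-07), from 3.33 ± 0.660 to 25.9 ± 8.54 CPM. In its list, glycerol and glycerophosphodiester use, 3 of 10 genes rose (4 adjusted over the list alone, median 0.30, camera adjusted p = 0.0451, adjusted p = 0.385 with an estimated correlation). That call was lost in 4 of the fits that left out a library, those without medium replicate 4, doxorubicin replicates 1 or 3, or QVD replicate 3 (adjusted p = 0.0650, 0.0797, 0.0541 and 0.0575). It was also lost with the term for the 8 unnamed genes (median 0.22, adjusted p = 0.0644) and with libraries low in them (median 0.17, adjusted p = 0.0532). Of 9 genes of the glucose and mannitol phosphotransferase system, 6 rose, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.0189, adjusted p = 0.263 with an estimated correlation). Of 21 genes for galactose, ribose, fucose and arabinose use, 9 rose, also when adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.263 with an estimated correlation). The median of that list was -0.01, against a mean of 0.44 and an upward test, and it ran from -0.07 without doxorubicin replicate 2 to 0.08 without doxorubicin replicate 3. With libraries low in the 8 unnamed genes the call was lost at a median of 0.06 (adjusted p = 0.0578). Fatty acid degradation genes rose in 5 of 8 cases, also when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.000780, adjusted p = 0.153 with an estimated correlation).

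Ribosomal protein genes rose in 43 of 54 cases, or 47 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 1.72e-10, adjusted p = 0.440 with an estimated correlation). rpsB (ECHS_RS00850) rose 1.49-fold (0.58 ± 0.12, adjusted p = 0.00184) and rpsM (ECHS_RS17195) rose 1.55-fold (0.63 ± 0.14, adjusted p = 0.00276). With a term for the 8 unnamed genes the list's median was 0.54, but 1 of the 54 genes passed the test and rpsM, at 0.55, did not (adjusted p = 0.0662, and 3.88e-08 to 0.166 over all alternatives). All 8 ATP synthase genes rose, also when adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.000335, adjusted p = 0.364 with an estimated correlation). Of 29 cell envelope stress genes, 16 rose and 1 fell, also when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 1.60e-06, adjusted p = 0.153 with an estimated correlation). Among them, spy (ECHS_RS09045), for a periplasmic chaperone, rose 6.66-fold (2.74 ± 0.21, adjusted p = 2.45e-07). The phage shock gene pspA (ECHS_RS07000) rose 3.31-fold (1.73 ± 0.15, adjusted p = 1.09e-06). The member that fell was degS (-0.30), an envelope protease gene. The biofilm-associated genes bssR (ECHS_RS04390) and bdm (ECHS_RS07730) rose 7.92-fold (2.99 ± 0.17, adjusted p = 4.75e-09) and 8.17-fold (3.03 ± 0.47, adjusted p = 0.000313). Medium replicates varied widely for bdm, with 12.9 ± 10.4 CPM against 2.45 ± 0.663 in the QVD supernatant and 20.0 ± 2.93 in the doxorubicin supernatant. Heat shock genes rose in 8 of 19 cases, or 9 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0132, adjusted p = 0.385 with an estimated correlation), or 0.13 without QVD replicate 2.

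Genes lower in the doxorubicin supernatant included metal, osmotic, acid and oxidative stress genes. Zinc uptake genes fell in 6 of 7 cases and zur, the zinc-responsive repressor gene, rose (0.39 ± 0.13), by the same counts when adjusted over the list alone. The list's median was -1.20 (camera adjusted p = 0.000549, adjusted p = 0.263 with an estimated correlation). Of 14 potassium and osmotic stress genes, 9 fell, also when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 1.24e-05, adjusted p = 0.153 with an estimated correlation). Of 11 acid resistance genes, 9 fell, also when adjusted over the list alone, with a median of -1.16 (camera adjusted p = 0.000187, adjusted p = 0.263 with an estimated correlation). Of 20 oxidative stress genes, 11 fell and katG, for a catalase, rose (0.34), by the same counts when adjusted over the list alone. The list's median was -0.34 (camera adjusted p = 0.000503, adjusted p = 0.263 with an estimated correlation). Of 40 genes in the siderophore and iron uptake list, 15 fell and 2 rose (16 and 2 adjusted over the list alone, median -0.08, camera adjusted p = 0.00332, adjusted p = 0.153 with an estimated correlation). The list also holds the iron-sulfur cluster assembly genes sufA, sufB, sufC, sufD, sufE and sufS. All of these were among the genes that fell (log2 -0.37 for sufD to -0.83 for sufB), so the falls are not of uptake genes alone. The list's median was -0.13, -0.14 and -0.13 without QVD replicates 1, 3 and 4. Of 26 RpoS-dependent general stress genes, 12 fell and raiA, for a ribosome-associated factor, rose (0.93), by the same counts when adjusted over the list alone. The list's median was -0.26 (camera adjusted p = 0.0222, adjusted p = 0.651 with an estimated correlation). The RpoS call was lost without QVD replicate 4 (adjusted p = 0.0502) and with fry (adjusted p = 0.151). The nitric oxide dioxygenase gene hmpA (ECHS_RS13350) fell by 2.08 ± 0.11 log2 units (adjusted p = 3.24e-09), from 217 ± 14.4 to 51.3 ± 3.64 CPM. pliG (ECHS_RS06300), for a periplasmic lysozyme inhibitor, fell by 1.99 ± 0.14 (adjusted p = 5.66e-08), from 134 ± 25.1 to 33.7 ± 1.06 CPM.

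DNA damage, fermentation and nucleotide genes were fixed for description in every comparison. Of 29 SOS genes, the LexA-controlled DNA damage response, 16 rose and ybfE fell (-0.60); adjusted over the list alone, 17 rose and 1 fell. The list's median was 0.25 (camera adjusted p = 0.000745, adjusted p = 0.385 with an estimated correlation). uvrA (ECHS_RS21175), for an excision repair subunit, rose 1.43-fold (0.52 ± 0.09, adjusted p = 0.000374). The antitoxin gene dinJ (ECHS_RS01265) rose 1.39-fold (0.47 ± 0.08, adjusted p = 0.000374). recA (ECHS_RS13985), for the recombinase that activates this response, rose 1.29-fold (0.36 ± 0.08, adjusted p = 0.00418). The division inhibitor gene sulA (ECHS_RS05230) had a log2 difference of -0.01 ± 0.09 (adjusted p = 0.943). Of 17 fermentation and formate genes, 5 rose, also when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0277, adjusted p = 0.364 with an estimated correlation). That call was lost without QVD replicate 2 (median 0.09, adjusted p = 0.0562). With the term for the 8 unnamed genes (median 0.16, adjusted p = 0.0613) and with libraries low in them (median 0.18, adjusted p = 0.148) it was lost at a median no smaller. With fry the adjusted p was 0.00416. grcA (ECHS_RS13510), for a spare glycyl radical domain of pyruvate formate-lyase, rose 3.74-fold (1.90 ± 0.21, adjusted p = 1.51e-05). The formate channel gene focA (ECHS_RS25375) rose 1.72-fold (0.79 ± 0.12, adjusted p = 0.000230). pflB (ECHS_RS04940), for pyruvate formate-lyase, rose 1.32-fold (0.41 ± 0.12, adjusted p = 0.0148), from 4890 ± 550 to 6476 ± 885 CPM. The pflB call was lost without doxorubicin replicate 1 or QVD replicates 1, 2 or 3 (adjusted p = 0.0516, 0.0545, 0.0801 and 0.0838) and with the term for the 8 unnamed genes (0.30, adjusted p = 0.223). Over all alternatives its adjusted p ran from 0.00219 to 0.668.

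Of 33 anaerobic respiration genes, 15 rose and 2 fell (16 and 3 adjusted over the list alone, median 0.44, camera adjusted p = 0.00125, adjusted p = 0.228 with an estimated correlation). The members that fell were torA (ECHS_RS05435) and torC, for trimethylamine N-oxide reduction. torA fell by 2.00 ± 0.20 (adjusted p = 2.43e-06), from 26.7 ± 2.86 to 6.77 ± 1.68 CPM. Of 17 purine biosynthesis genes, 6 rose and purU fell (-0.43), or 10 and 1 adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.00886, adjusted p = 0.565 with an estimated correlation, adjusted p = 0.0851 with fry). purD (ECHS_RS20860) rose 1.71-fold (0.78 ± 0.13) and prs (ECHS_RS06455) 1.45-fold (0.53 ± 0.09), both with an adjusted p of 0.000319. purF (ECHS_RS12185), for the pathway's committed step, differed by 0.50 ± 0.20 (adjusted p = 0.0734). It passed without medium replicates 3 or 4 or doxorubicin replicate 1 (adjusted p = 0.0472, 0.0247 and 0.0392), with DESeq2 (adjusted p = 0.0451) and with a fit of both groups alone (adjusted p = 0.0114). The highest adjusted p of purF was 0.565, with L1 libraries alone. The pyrimidine list did not pass (median 0.10, camera adjusted p = 0.153, adjusted p = 0.551 with an estimated correlation, adjusted p = 0.0385 with fry), with 3 of 9 genes higher, also when adjusted over the list alone. carB (ECHS_RS00180), for carbamoyl phosphate synthase, which also feeds arginine synthesis, rose 2.26-fold (1.17 ± 0.15, adjusted p = 3.89e-05). pyrF (ECHS_RS06870) rose 1.39-fold (0.48 ± 0.10, adjusted p = 0.00158). Of 24 nitrogen limitation genes, 7 rose and 1 fell, also when adjusted over the list alone (median 0.15, camera adjusted p = 0.0376, adjusted p = 0.501 with an estimated correlation). The nitrogen limitation call was lost without medium replicate 4 (adjusted p = 0.0545), without doxorubicin replicate 2 (adjusted p = 0.0664) and, at a larger median of 0.22, with the term for the 8 unnamed genes (adjusted p = 0.0574). Its lowest adjusted p was 0.0187, from the libraries low in those genes.

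In this comparison 25 of the 52 tested lists were called, 18 up and 7 down, and 1, arginine biosynthesis, was called with an estimated correlation. Of the other splits of the 8 libraries, the 18 with 2 libraries of each group on a side, which cancel the group difference, called 0 to 5 lists. The 16 that keep 3 libraries of a group together, and so part of the difference, called 15 to 24. The groups did not overlap for 1306 genes (37.8%), against 2.86% by chance. With a term for the 8 unnamed genes 494 genes were called in place of 1123, and 253 were called from the 7 libraries low in them, of which 1 came from the QVD supernatant. With that 1 QVD library, 10 named genes did not pass although most changes were about as large or larger, at 0.64 for rpsB, 0.65 for rpsM, 0.53 for dinJ, 0.62 for uvrA, 0.80 for purD, 0.53 for prs, 0.56 for pyrF and 0.49 for recA. The changes of focA (0.50) and pflB (0.18) were smaller there. With a term for the mean level of the ribosomal protein genes, which differs between the groups, 693 genes were called. Among the 3 medium, 2 doxorubicin and 3 QVD libraries whose names carry L1, a suffix the labels do not explain, 394 genes were called, and rpsB and recA were not, with changes of 0.53 and 0.33 close to those of all libraries (adjusted p = 0.0794 and 0.119). Over all alternatives these ran from 6.66e-08 to 0.125 for rpsB and from 0.000144 to 0.119 for recA.

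**Figure D2:**
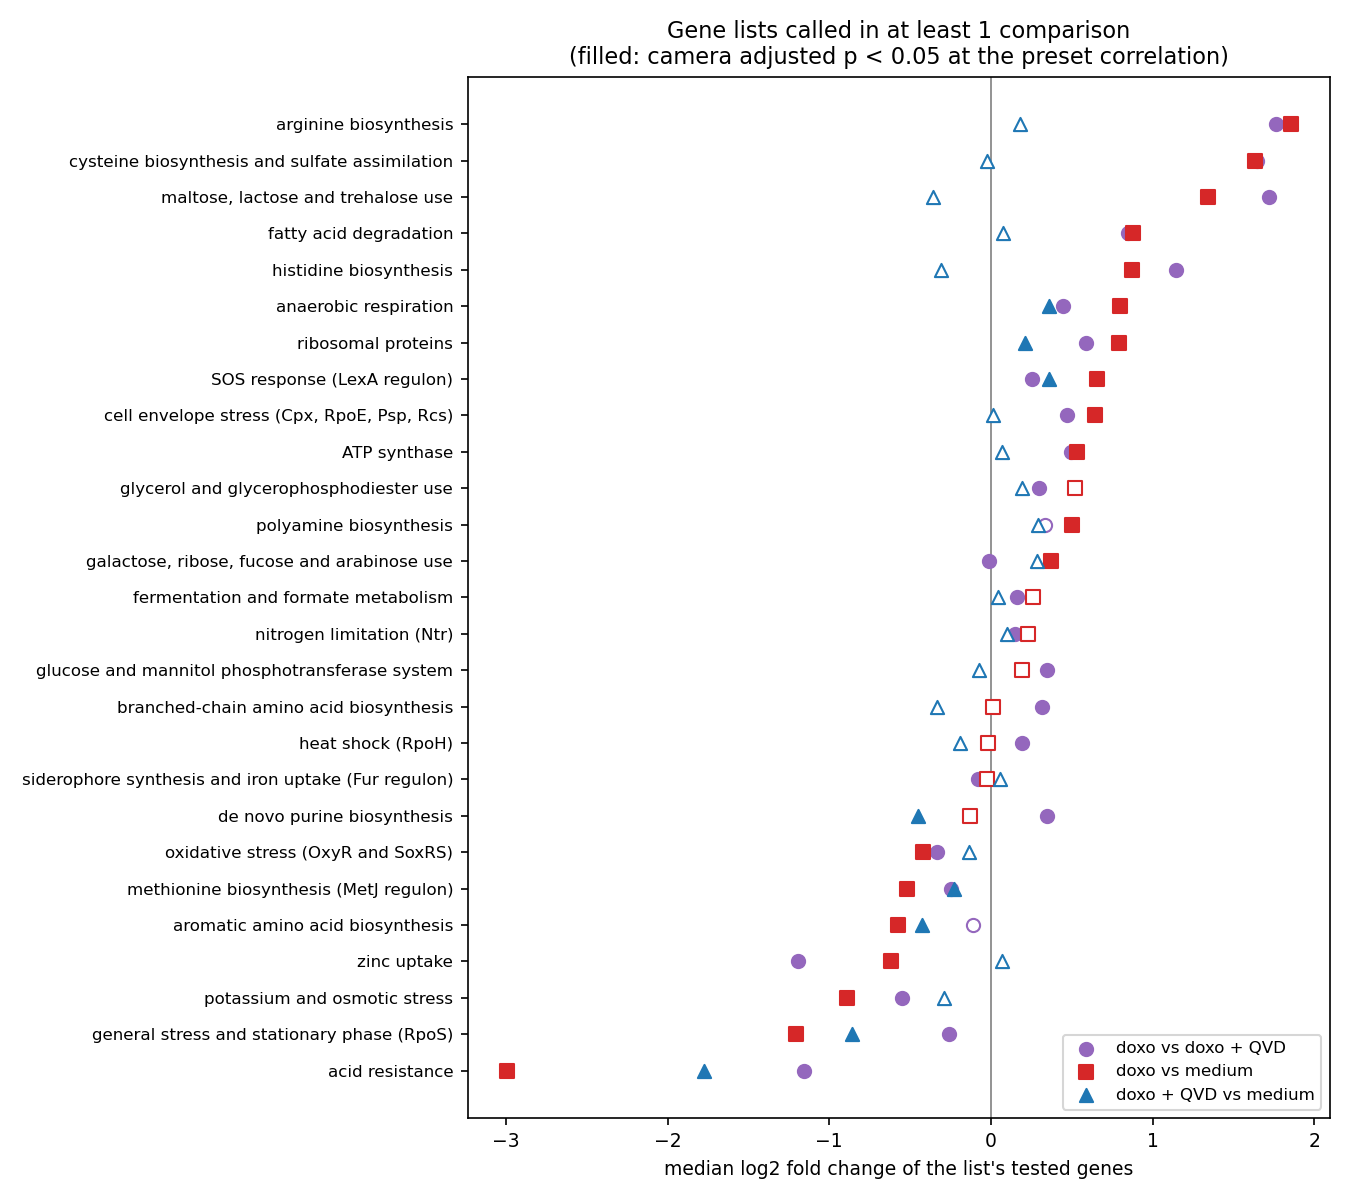
Median log2 fold change of the tested genes of each list called in at least 1 comparison, with circles for the doxorubicin against the QVD supernatant, squares for the doxorubicin supernatant against medium and triangles for the QVD supernatant against medium. Filled symbols mark lists called by camera at its preset correlation; the cysteine list lies at 1.64 and 1.63 in the comparisons of the doxorubicin supernatant and at -0.03 in the QVD supernatant against medium.

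The doxorubicin supernatant against medium compares the supernatant of dying, drug-treated cells with medium that held no cells. No group held supernatant of untreated cells, so effects of the cells, their death and the drug cannot be told apart here. Sulfate assimilation, arginine, maltodextrin, ribosomal protein and SOS genes were higher in the supernatant, and acid resistance, general stress and aromatic amino acid genes were lower. Of these list calls arginine alone was made with an estimated correlation (adjusted p = 0.0590 to 0.529 for the others). cysP rose 20.6-fold (log2 4.36 ± 0.15 SE, adjusted p = 1.50e-11) from 18.7 ± 3.47 CPM in medium, and glpA rose 20.0-fold (4.32 ± 0.31, adjusted p = 1.99e-08) from 1.31 ± 0.785 CPM. The acid chaperone genes hdeB (ECHS_RS18265) and hdeA (ECHS_RS18270) fell, with log2 changes of -4.33 ± 0.25 and -4.22 ± 0.20 (adjusted p = 3.48e-09 and 2.17e-10), hdeA from 135 ± 35.3 to 7.30 ± 1.69 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1000 genes were higher and 950 lower, and 204 and 224 of these differed at least 2-fold. The balance turned without medium replicate 2 (837 higher, 905 lower) or 3 (832, 914) and without QVD replicate 1 (919, 974), 2 (918, 972), 3 (906, 974) or 4 (914, 979). It also turned with L1 libraries alone (607, 640) and with libraries low in the 8 unnamed genes (636, 662). With a term for the mean level of the ribosomal protein genes 916 genes were called in place of 1950.

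Cysteine and sulfate genes rose in 12 of 17 cases, while cysE and cysQ fell (-0.25 and -0.68), by the same counts when adjusted over the list alone, with a median of 1.63 (camera adjusted p = 4.87e-05, adjusted p = 0.315 with an estimated correlation). Besides cysP, cysJ rose 14.2-fold (3.82 ± 0.12, adjusted p = 1.98e-12). tcyP (ECHS_RS08965), for a cystine importer, rose 8.40-fold (3.07 ± 0.13, adjusted p = 4.73e-11). yeeE (ECHS_RS10690) rose by 3.05 ± 0.15 log2 units (adjusted p = 3.93e-10) and bssR rose 14.6-fold (3.86 ± 0.18, adjusted p = 2.11e-10). Arginine genes rose in 7 of 8 cases, also when adjusted over the list alone, with a median of 1.85 (camera adjusted p = 8.96e-06, adjusted p = 0.0417 with an estimated correlation). argG (ECHS_RS16580), for argininosuccinate synthase, rose 4.10-fold (2.04 ± 0.13, adjusted p = 4.92e-09) and argA 3.53-fold (1.82 ± 0.08, adjusted p = 8.03e-11). All 8 histidine genes rose, also when adjusted over the list alone (median 0.87, camera adjusted p = 0.000539, adjusted p = 0.465 with an estimated correlation). By contrast, 13 of 18 aromatic amino acid genes fell and 2 rose, also when adjusted over the list alone (median -0.58, camera adjusted p = 0.000448, adjusted p = 0.0590 with an estimated correlation). Of 11 methionine genes, 9 fell, also when adjusted over the list alone (median -0.52, camera adjusted p = 0.00116, adjusted p = 0.280 with an estimated correlation). Polyamine biosynthesis genes rose in 4 of 5 cases, or 5 adjusted over the list alone (median 0.50, camera adjusted p = 0.0447, adjusted p = 0.529 with an estimated correlation). The polyamine call was lost without medium replicates 2 or 3 (adjusted p = 0.0632 and 0.0594), doxorubicin replicates 1, 3 or 4 (adjusted p = 0.0525, 0.0543 and 0.0546) or QVD replicates 3 or 4 (adjusted p = 0.0509 and 0.0518).

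General stress genes fell in 23 of 26 cases while cstA, for a peptide and pyruvate transporter, rose (0.61), by the same counts when adjusted over the list alone, with a median of -1.21 (camera adjusted p = 2.27e-08, adjusted p = 0.393 with an estimated correlation). dps (ECHS_RS04255), for a DNA-binding ferritin, fell by 3.11 ± 0.18 log2 units (adjusted p = 5.76e-09), and elaB (ECHS_RS11940) fell by 2.45 ± 0.16 (adjusted p = 1.11e-08). Acid resistance genes fell in 10 of 11 cases, also when adjusted over the list alone, with a median of -2.99 (camera adjusted p = 1.51e-06, adjusted p = 0.280 with an estimated correlation). Potassium and osmotic stress genes fell in 10 of 14 cases, also when adjusted over the list alone (median -0.89, camera adjusted p = 0.000150, adjusted p = 0.270 with an estimated correlation). Oxidative stress genes fell in 12 of 20 cases, also when adjusted over the list alone (median -0.42, camera adjusted p = 0.000886, adjusted p = 0.315 with an estimated correlation). Zinc uptake genes fell in 5 of 7 cases while zur rose (0.59), by the same counts when adjusted over the list alone (median -0.62, camera adjusted p = 0.0346, adjusted p = 0.529 with an estimated correlation). hmpA fell by 3.92 ± 0.12 log2 units (adjusted p = 1.98e-12) from 775 ± 141 CPM in medium, and ytfE (ECHS_RS21975), for repair of iron-sulfur clusters, fell by 3.60 ± 0.16 (adjusted p = 1.33e-10). poxB (ECHS_RS04775), for pyruvate oxidase, and yahO (ECHS_RS01990) each fell by 3.45 log2 units (SE 0.26 and 0.32, adjusted p = 2.99e-07 and 3.86e-07).

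SOS genes rose in 23 of 29 cases, also when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 2.27e-08, adjusted p = 0.280 with an estimated correlation). The recombination gene recN (ECHS_RS13700) rose 2.40-fold (1.26 ± 0.11, adjusted p = 1.87e-07) and the repressor gene lexA (ECHS_RS21095) 2.00-fold (1.00 ± 0.08, adjusted p = 3.80e-08). recA rose 1.69-fold (0.76 ± 0.08, adjusted p = 2.16e-06) and sulA rose 1.74-fold (0.80 ± 0.09, adjusted p = 1.80e-06). Ribosomal protein genes rose in 51 of 54 cases, or 52 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 2.79e-10, adjusted p = 0.529 with an estimated correlation). rpsP (ECHS_RS13665) rose by 0.81 ± 0.12 and rpsB by 0.79 ± 0.12 log2 units (adjusted p = 4.06e-05 and 4.47e-05). All 8 ATP synthase genes rose, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.00449, adjusted p = 0.529 with an estimated correlation). Of 29 envelope stress genes, 21 rose and 5 fell, also when adjusted over the list alone (median 0.64, camera adjusted p = 0.00127, adjusted p = 0.351 with an estimated correlation). Anaerobic respiration genes rose in 19 of 33 cases, also when adjusted over the list alone (median 0.80, camera adjusted p = 0.000446, adjusted p = 0.280 with an estimated correlation). Maltose, lactose and trehalose genes rose in 10 of 14 cases, also when adjusted over the list alone (median 1.34, camera adjusted p = 5.76e-05, adjusted p = 0.280 with an estimated correlation). Fatty acid degradation genes rose in 7 of 8 cases, also when adjusted over the list alone (median 0.88, camera adjusted p = 0.00963, adjusted p = 0.280 with an estimated correlation). Galactose, ribose, fucose and arabinose genes rose in 12 of 21 cases and fell in 2, also when adjusted over the list alone (median 0.37, camera adjusted p = 0.00963, adjusted p = 0.280 with an estimated correlation).

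The fermentation list did not pass camera against medium (median 0.26, camera adjusted p = 0.172, adjusted p = 0.537 with an estimated correlation, adjusted p = 0.00154 with fry), although 7 of 17 genes rose and 1 fell, also when adjusted over the list alone. grcA rose 6.74-fold (2.75 ± 0.22, adjusted p = 1.85e-07), focA 2.10-fold (1.07 ± 0.13, adjusted p = 3.57e-06) and pflB 1.41-fold (0.50 ± 0.12, adjusted p = 0.00187). The purine list did not pass (median -0.13, camera adjusted p = 0.272, adjusted p = 0.858 with an estimated correlation), with 2 of 17 genes higher and 7 lower, also when adjusted over the list alone. purC (ECHS_RS12890) fell by 0.63 ± 0.12 log2 units (adjusted p = 0.000497) and purU (ECHS_RS06600) fell by 0.57 ± 0.08 (adjusted p = 2.64e-05). purF differed by 0.28 ± 0.20 (adjusted p = 0.247) and passed without medium replicate 4 (0.50, adjusted p = 0.0213, against at most 0.855 in other alternatives). The pyrimidine list did not pass (median 0.16, camera adjusted p = 0.369, adjusted p = 0.754 with an estimated correlation, adjusted p = 0.00798 with fry), with 4 of 9 genes higher and 2 lower, also when adjusted over the list alone. carB rose 3.82-fold (1.93 ± 0.16, adjusted p = 8.67e-08) and pyrF 1.71-fold (0.77 ± 0.10, adjusted p = 6.82e-06). In all, 19 of 52 lists were called against medium, 12 up and 7 down, of which arginine biosynthesis alone was called with an estimated correlation. The 18 splits with 2 libraries of each group on a side called 0 to 14 lists. The groups did not overlap for 1618 genes (46.9%), against 2.86% by chance, and 1247 genes were called among the libraries whose names carry L1.

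**Figure D3:**
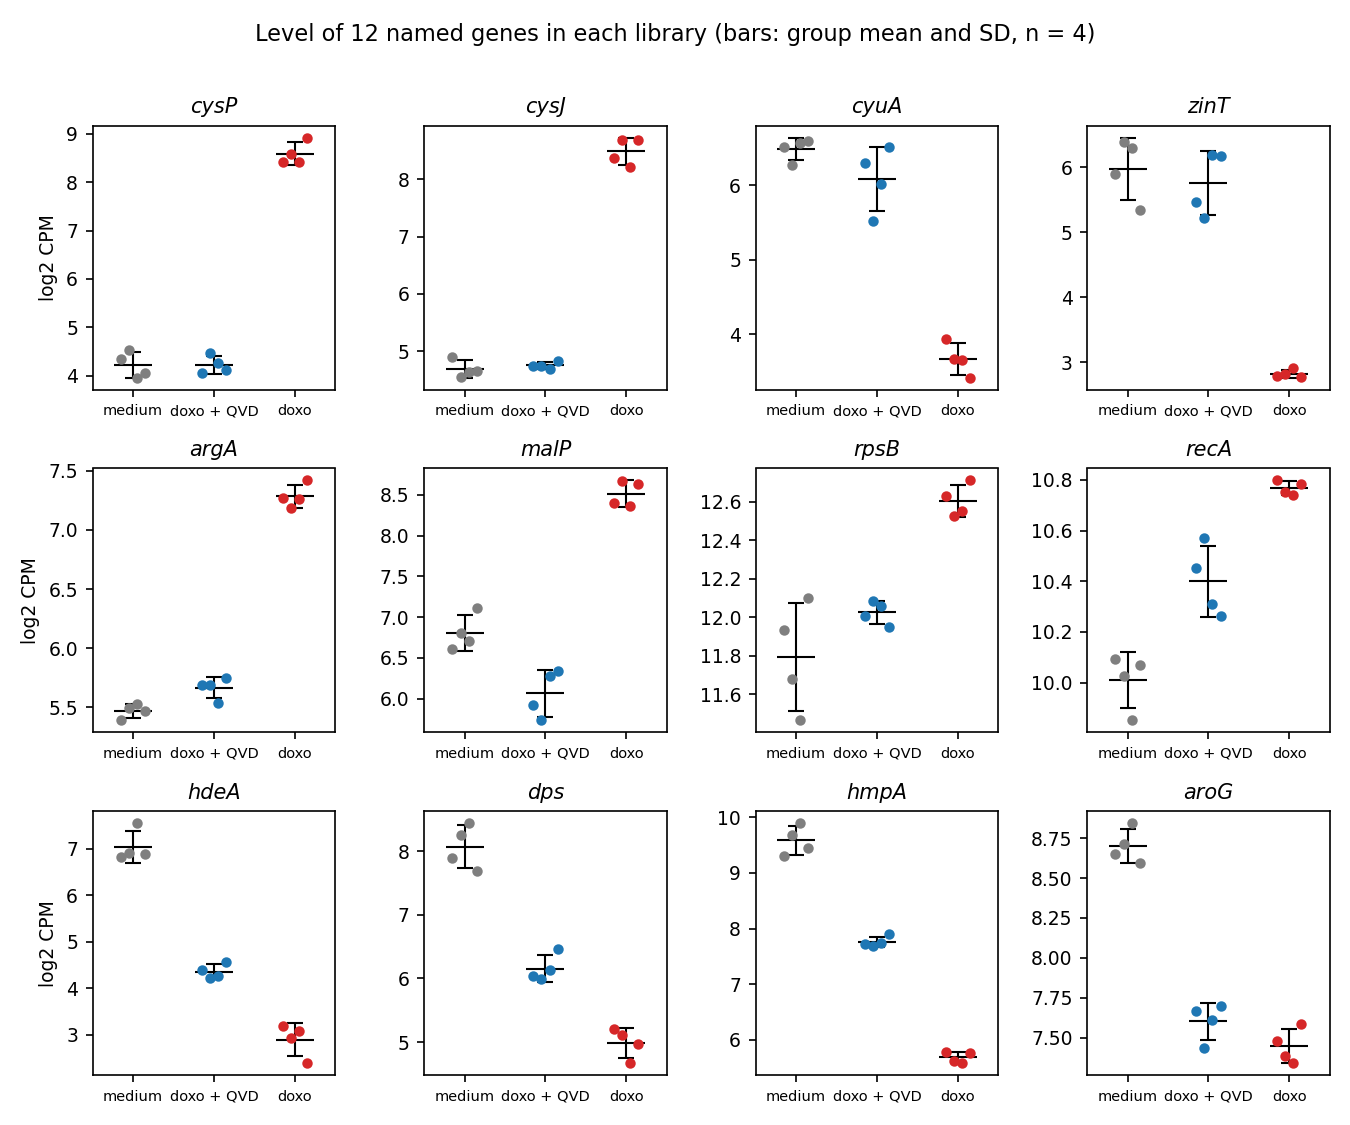
Level of 12 named genes in log2 CPM for each library (points) in medium, the QVD supernatant and the doxorubicin supernatant, with bars for the group mean and SD (n = 4); the vertical axes differ between panels and do not start at 0. cysP stands at 386 CPM in the doxorubicin supernatant against 18.7 in medium and 18.6 in the QVD supernatant, whereas hdeA, dps and hmpA fall in steps from medium to the QVD and doxorubicin supernatants.

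The QVD supernatant against medium compares the supernatant of drug-treated cells whose death was inhibited with no cells. Without a supernatant of untreated cells, effects of the cells, the drug and QVD cannot be told apart in it. General stress and acid resistance genes were lower and SOS genes higher in the QVD supernatant, whereas the cysteine list showed no net change (4 of 17 higher, 3 lower, by camera adjusted p = 0.881). With an estimated correlation none of these lists was called (adjusted p = 0.620 for each of those 3), and 8 of the 18 splits with 2 libraries of each group on a side called at least as many lists as the groups. The largest rises included cspH (ECHS_RS05390) and cspG (ECHS_RS05395), of the cold shock protein family, at 5.65-fold (adjusted p = 5.92e-06) and 3.62-fold (log2 1.86 ± 0.43 SE, adjusted p = 0.00654). The acid shock gene asr (ECHS_RS08295) rose 4.37-fold (2.13 ± 0.19, adjusted p = 1.07e-06) and ydfK (ECHS_RS08085), which has a near-identical copy and so an uncertain count, rose 3.87-fold (1.95 ± 0.17, adjusted p = 1.07e-06). hdeB and hdeA fell, with log2 changes of -2.78 ± 0.22 and -2.73 ± 0.17 (adjusted p = 6.34e-07 and 9.02e-08), and bdm fell by 2.38 ± 0.48 (adjusted p = 0.00144). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 684 genes were higher and 774 lower, and 81 and 109 of these differed at least 2-fold.

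General stress genes fell in 24 of 26 cases while cstA rose (0.47), by the same counts when adjusted over the list alone, with a median of -0.86 (camera adjusted p = 6.50e-10, adjusted p = 0.620 with an estimated correlation). dps fell by 1.94 ± 0.16 log2 units (adjusted p = 1.18e-06) and osmC (ECHS_RS07735), for a peroxidase, fell by 1.38 ± 0.12 (adjusted p = 1.13e-06). Acid resistance genes fell in 9 of 11 cases, also when adjusted over the list alone, with a median of -1.77 (camera adjusted p = 2.52e-06, adjusted p = 0.620 with an estimated correlation). The glutamate decarboxylase gene gadB (ECHS_RS07790), nearly identical to gadA and so of uncertain count, fell by 2.33 ± 0.19 (adjusted p = 6.76e-07). SOS genes rose in 21 of 29 cases, also when adjusted over the list alone, with a median of 0.36 (camera adjusted p = 2.35e-07, adjusted p = 0.620 with an estimated correlation). yafP (ECHS_RS01300) rose 2.96-fold (1.57 ± 0.14, adjusted p = 1.07e-06), sulA 1.75-fold (0.81 ± 0.09, adjusted p = 5.34e-06) and recA 1.31-fold (0.39 ± 0.08, adjusted p = 0.00164). Purine biosynthesis genes fell in 11 of 17 cases, or 12 adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.000702, adjusted p = 0.745 with an estimated correlation). purE (ECHS_RS02935) fell by 0.92 ± 0.13 log2 units (adjusted p = 5.83e-05) and purK (ECHS_RS02930) fell by 0.87 ± 0.12 (adjusted p = 3.43e-05). purF differed by -0.21 ± 0.20 (adjusted p = 0.413).

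Aromatic amino acid genes fell in 13 of 18 cases and rose in 2 (13 and 3 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.00239, adjusted p = 0.175 with an estimated correlation). aroG (ECHS_RS03950), for an enzyme of the pathway's entry step, fell by 1.10 ± 0.08 log2 units (adjusted p = 3.12e-07) and aroA (ECHS_RS04965) fell by 0.59 ± 0.07 (adjusted p = 1.03e-05). Ribosomal protein genes rose in 4 of 54 cases, or 1 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.00423, adjusted p = 0.911 with an estimated correlation). That call was lost without medium replicate 2 (median 0.12, adjusted p = 0.0805) or medium replicate 3 (median 0.07, adjusted p = 0.178), with libraries low in the 8 unnamed genes (median 0.08, adjusted p = 0.417) and with fry (adjusted p = 0.292). Without medium replicate 4 the median was 0.39. rpmH (ECHS_RS19295) rose by 0.58 ± 0.12 and rpsU (ECHS_RS16025) by 0.43 ± 0.12 log2 units (adjusted p = 0.000957 and 0.00879), rpsU, at 0.40, not among L1 libraries (adjusted p = 0.0561, and 1.93e-05 to 0.697 over all alternatives). Anaerobic respiration genes rose in 9 of 33 cases and fell in 2 (9 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0301, adjusted p = 0.620 with an estimated correlation). The call was lost without medium replicate 4 (adjusted p = 0.0732). Of 11 methionine genes, 6 fell, also when adjusted over the list alone (median -0.23, camera adjusted p = 0.0318, adjusted p = 0.620 with an estimated correlation). The call was lost without medium replicate 2 (adjusted p = 0.0523). The fermentation list did not pass (median 0.05, mean -0.01, camera adjusted p = 0.849, adjusted p = 0.928 with an estimated correlation), with 2 of 17 genes higher and 2 lower, also when adjusted over the list alone. pflA (ECHS_RS04935), for the activator of pyruvate formate-lyase, rose by 0.58 ± 0.10 and ldhA (ECHS_RS07250), for lactate dehydrogenase, fell by 0.63 ± 0.15 log2 units (adjusted p = 0.000228 and 0.00301). pflB differed by 0.09 ± 0.12 (adjusted p = 0.544). The pyrimidine list did not pass (median 0.12, camera adjusted p = 0.723, adjusted p = 0.922 with an estimated correlation), with 3 of 9 genes higher, such as carB (0.76 ± 0.15, adjusted p = 0.000993), and pyrC (ECHS_RS05815) lower (-0.39 ± 0.10, adjusted p = 0.00590), also when adjusted over the list alone.

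In this comparison 8 of 52 lists were called, 3 up and 5 down, none with an estimated correlation. The groups did not overlap for 1295 genes (37.5%), against 2.86% by chance, and 1024 genes were called among the libraries whose names carry L1. The libraries low in the 8 unnamed genes set 1 QVD library against 2 medium libraries, too few to judge a lost call, and 68 genes were called from them. Of 11 named genes that did not pass there, changes were -0.89 for purK, -0.87 for purE, 1.68 for cspG, -0.53 for aroA, -0.40 for pyrC and 0.50 for pflA, close to those of all libraries. They were smaller for rpmH (0.41), carB (0.51), ldhA (-0.33), recA (0.24) and rpsU (0.21).

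The comparisons were then set beside each other to ask which genes stood apart in the doxorubicin supernatant and which responded to both supernatants. Against both other media, 448 genes were higher and 375 lower in the doxorubicin supernatant, 823 in all, cysP, cysJ, argA, malP and hmpA among them, and 53 genes differed in opposite directions. Independent lists of these sizes would share 170 higher and 148 lower genes, and simulated unchanged groups sharing the doxorubicin libraries gave a mean of 0.02 genes, at most 1. The balance turned without medium replicate 2 (388 higher, 431 lower) or 3 (396, 438) and without QVD replicate 1 (338, 390), 2 (349, 404), 3 (316, 371) or 4 (310, 351), and with libraries low in the 8 unnamed genes (106, 127). Among the libraries whose names carry L1 the count was 300. Both supernatants differed from medium in the same direction for 1108 genes, 509 higher and 599 lower, with 27 in opposite directions. hdeA, hdeB, dps, sulA, recA and aroG were among these shared genes. Independent lists would share 198 higher and 213 lower genes, and simulated unchanged groups against the same medium libraries shared 0. In the simulations no gene differed between groups, so overlaps near 0 were fixed in advance. The simulations therefore do not show the overlap that shared libraries give when many genes differ. The figures for independent lists leave the shared libraries out as well. The simulations also held no factor common to the genes of a library, so they do not show what overlap such a factor would give. The change against medium was larger in the doxorubicin supernatant for 750 of the 1108 genes, and for 375 of them the supernatants also differed from each other by the test.

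Across the 3451 genes, which are not independent replicates, the log2 fold changes of the supernatants against medium had a correlation of 0.73. Simulated unchanged groups against the same controls gave 0.49 (0.41 to 0.56 in 50 simulations), and splitting the controls so that each comparison used its own gave 0.55 to 0.76 over 6 splits. The covariance was 0.283, against 0.0143 simulated, a difference of 0.268, and it was 0.214 to 0.285 with split controls. The sign was the same for 79.5% of genes, against 66.4% in the simulations.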

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

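The test of the 8 unnamed genes below was chosen only after the result was seen. Dixon's Q was computed for 94 values in each of the 3 groups of 4 libraries against its tabulated critical value, and chance flags about 1 in 20. Of 282 values tested, 13 exceeded it, against 14.1 by chance, with 7 in medium, 4 in the doxorubicin supernatant and 2 in the QVD supernatant, against 4.7 each by chance. In medium, Q was 0.956 for yahO (replicate 4, 4.22 against 5.24 to 5.28 log2 CPM), 0.893 for purK (replicate 4), 0.842 for rpsU (replicate 4) and 0.882 for hdeA (replicate 3). Among list means in medium it was 0.884 for cysteine and sulfate genes, 0.880 for fatty acid degradation and 0.861 for maltose, lactose and trehalose genes (5.60 against 4.30 to 4.48), each for replicate 4. In the doxorubicin supernatant Q was 0.856 for the share of counts from the 8 unnamed genes (replicate 3, 0.169% against 0.0441% to 0.0620%), 0.871 for rpsM (replicate 2), 0.906 for the mean of anaerobic respiration genes and 0.849 for that of fatty acid degradation (both replicate 1). In the QVD supernatant it was 0.910 for purE (replicate 4) and 0.888 for glpA (replicate 2). Medium replicate 4 gave 6 of the 7 values flagged in medium. The values flagged in a library are not independent of each other, and nothing was left out because of them.

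The 8 unnamed genes and dnaJ differed widely among libraries of the same group. The suffix of the library names does not account for all of it, since the share of the 8 genes differed 10.2-fold among medium libraries with the suffix L1. In the QVD supernatant the share did follow the suffix, at 0.402% to 1.14% with L1 and 0.117% with L3. The L4 libraries were low as well, at 0.0863% in medium and 0.0441% and 0.169% in the doxorubicin supernatant. Doxorubicin libraries with L1 were also low (0.0569% and 0.0620%). A part that follows the suffix is not excluded. All 4 doxorubicin libraries were low, so part of the difference between the supernatants could follow this factor and not the death of the cells. What differed between these cultures or libraries remains open, and no biological explanation was tested.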

How the results depend on the processing

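The term for the 8 unnamed genes and the fit of libraries low in them were chosen only after the result was seen. No named gene called with all libraries changed sign in an alternative, but the balance of higher and lower genes turned in the fits named above, and the median of the galactose list (-0.01) changed sign in some, such as 0.06 with low-share libraries. For the doxorubicin against the QVD supernatant the count of 1123 genes was weaker with L1 libraries alone (394), with the term for the 8 unnamed genes (494, of which 489 were among the 1123) and with low-share libraries alone (253, of which 249). For the doxorubicin supernatant against medium, 1950 was weaker with L1 libraries alone (1247) and low-share libraries alone (1298). For the QVD supernatant against medium, 1458 was weaker with low-share libraries alone (68). The 823 genes that differed from both other media were weaker in these fits (L1 alone 300, term 410, low-share alone 233). L1 libraries include 2 doxorubicin libraries and low-share libraries 1 QVD library, so these fits hold fewer samples. For the term the cause was not tested. A term for the mean level of the ribosomal protein genes, which differs between the groups, left 693, 916 and 1428 genes in the 3 comparisons, and whether it removes growth state or part of the group difference was not tested. With the term for the 8 unnamed genes all 1123 genes kept their sign, and the correlation of the log2 changes was 0.93. List calls were weaker with an estimated correlation (1, 1 and 0 lists, from 25, 19 and 8), and stronger with fry for the comparisons with medium (36 and 22); the cause was not tested. Leaving out each library in turn gave 859 (without doxorubicin replicate 4) to 1319 genes (without medium replicate 4) for the doxorubicin against the QVD supernatant. Against medium it gave 1742 to 2120 for the doxorubicin and 1231 to 1677 for the QVD supernatant, and 661 to 979 for genes that differed from both. Lists ranged over 23 to 26, 18 to 20 and 6 to 9, and the correlation of the supernatant responses over 0.70 to 0.78. DESeq2 gave 1227, 1988 and 1519 genes, RLE scaling 1124, 1949 and 1447, and the suffix term 1049, 1915 and 1419. With the replicate number as a block 1055, 1912 and 1411 genes were called and no named gene or list changed its call. Replicates with the same number were not closer than others, with correlations of -0.15 to 0.19 over 12 pairs, so they were not treated as paired. Of 146 results for single genes, 106 were unchanged in every setting, and low-share libraries alone weakened 34. Of these, norV and zntA in the doxorubicin supernatant against medium compare 4 with 2 libraries, and the others rest on 1 QVD library.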

Other observations

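The tests of less cysteine and of the 8 unnamed genes were chosen only after the result was seen, and the genes in this part likewise. Among genes that respond to nitric oxide, 5 were picked because of their values, and no list of such genes was tested. Against medium hmpA had log2 changes of -3.92 in the doxorubicin and -1.84 in the QVD supernatant, ytfE -3.60 and -2.20, ygbA -2.54 and -1.31 and hcp -1.68 and -1.41. For norV they were -0.94 (adjusted p = 0.00797) and -0.83 (adjusted p = 0.0179). The call in the doxorubicin supernatant was lost with low-share libraries alone. The call in the QVD supernatant was lost without medium replicate 3 (adjusted p = 0.0672) or QVD replicate 4 (adjusted p = 0.0547) and with L1 libraries alone (adjusted p = 0.0551). Between the supernatants hcp and norV did not pass (adjusted p = 0.347 and 0.806). Both were low, with group means of 3.10 to 9.83 CPM for hcp and 3.26 to 6.43 CPM for norV. Against medium the iron-sulfur cluster assembly genes had log2 changes of -2.15 in the doxorubicin and -1.32 in the QVD supernatant for sufB, and of -2.02 and -1.49 for sufA.

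zinT, znuA and ykgM, induced when zinc is scarce, had log2 changes of -3.04, -1.78 and -1.95 in the doxorubicin against the QVD supernatant, and the zinc exporter gene zntA had 1.90 (adjusted p = 0.00569). The zntA call was lost at 1.57 with the term for the 8 unnamed genes (adjusted p = 0.0575) and at 1.98 with L1 libraries alone (adjusted p = 0.0501), and the copper and heavy metal efflux list that holds it did not pass (1 of 7 higher, median 0.01, camera adjusted p = 0.622, adjusted p = 0.702 with an estimated correlation). Against medium zntA had 1.16 (adjusted p = 0.0279), lost without medium replicates 1, 2 or 3 (adjusted p = 0.0547, 0.0716 and 0.0815) or doxorubicin replicates 1 or 4 (adjusted p = 0.0623 and 0.0502), with L1 libraries alone (1.08, adjusted p = 0.129), with low-share libraries alone (0.86, adjusted p = 0.274) and with a fit of both groups alone (1.15, adjusted p = 0.0731). Among anaerobic genes, napF (1.77), napA (1.17), frdA (1.17) and nikA (1.39) were higher in the doxorubicin than in the QVD supernatant, whereas torA (-2.00) and torC (-3.22) were lower. torA and torC were higher in the QVD supernatant than in medium (1.74 and 2.64).

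Cysteine and sulfate genes were higher in the doxorubicin supernatant than in both other media. With a term for the ribosomal protein genes, the median stayed at 1.73 against the QVD supernatant (camera adjusted p = 2.04e-12 at the preset correlation). Without the term, that list was not called with an estimated correlation. The mean level of the ribosomal genes had an SD of 0.031 log2 units within each supernatant, against 0.43 in medium. The term's slope thus rests mainly on the medium libraries, and the fit cannot exclude growth state. cyuA and cyuP were considered because they were among the largest falls. Their fall, whose smallest log2 change against either other medium was -2.49, is consistent with less cysteine being available to the cells, as a hypothesis that cysteine measurements could test. No group held medium with the drug or QVD added but no cells, and none held supernatant of untreated cells. Effects of carried-over drug and of QVD itself therefore remain open, as do, against medium, effects of the cells apart from their death.

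General stress genes were lower in both supernatants than in medium. A difference in growth state may explain part of it. The ribosomal term changed the median in the doxorubicin supernatant from -1.21 to -0.63 (camera adjusted p = 4.12e-07 at the preset correlation). In the QVD supernatant the median went from -0.86 to -0.68 (camera adjusted p = 2.43e-10). Without the term, neither list call held with an estimated correlation. Whether growth state accounts for the whole fall cannot be told from that term. The mean level of the ribosomal genes had an SD of 0.031 log2 units within each supernatant, against 0.43 in medium, so its slope rests mainly on the medium libraries. The difference between the supernatants, -0.26, did not remain with that term (0.06, adjusted p = 0.891). A factor followed by the 8 unnamed genes does not account for the fall, with a median of -1.24 in the doxorubicin supernatant against medium.

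Whether any grouping of the libraries would give such counts was tested by every split of the 8 libraries of a comparison into 4 and 4, 35 with the real split. For genes, 1 of 35 splits, the real split, reached the real count in each comparison, with 1123 against at most 0 in the others for the supernatants, 1950 against 1 for the doxorubicin supernatant and medium, and 1458 against 1 for the QVD supernatant and medium. For the genes that differed from both other media it was 1 of 100 regroupings, 823 against at most 0. In the other splits a real group difference adds to the spread within each side, which lowers their gene counts. Those counts therefore do not show how many genes chance would give, and 1 of 35 is the lowest share possible. The splits cannot tell the death of the cells from any other factor common to the libraries of a group. For lists, 1 of 35 splits reached 25 between the supernatants, with 24 as the highest other, from a split that keeps 3 libraries of each group together and so part of the group difference. The 18 splits with 2 libraries of each group on a side, which cancel it, called at most 5. For the doxorubicin supernatant against medium 9 of 35 splits reached 19 lists (highest other 20). Apart from the real split, these all keep 3 libraries of each group together. The 18 that cancel the difference called at most 14. By the rule set before the data were examined, the share of splits leaves chance open for this count. Sorting the splits by the libraries kept together was not part of that rule. For the QVD supernatant against medium 18 of 35 reached 8 (highest other 16), among them 8 of the 18 splits that cancel the difference (up to 15 lists). Chance is therefore not excluded for the list count of either supernatant against medium.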
